A study of Mus musculus with 6 samples.

How the data were processed

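Whole ovaries of C57BL/6 mice at day 1 were profiled by RNA sequencing in 6 libraries, 3 from animals with floxed Hnrnpl and a Stra8-cre transgene (cKO) and 3 from wild type animals, as the sample titles and genotype labels give them. Stra8-cre is a transgene that expresses Cre recombinase in germ cells. Per the labels' protocols, ovaries were lysed directly in a buffer with a collagenase blend and DNase, and libraries were made from amplified cDNA with a kit for low input. The same protocol text speaks of a hormone challenge, and what it was is not given in the sources used here. Nothing in the labels says whether the libraries of a group came from separate animals. The p-values of single genes therefore measure only the spread between these libraries.

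The authors deposited 1 table of FPKM values (fragments scaled to transcript length and to the number of mapped fragments) with 25164 gene symbols and 6 columns, and each column name matched 1 sample title. The submitters' processing notes name the mm10 build, STAR 2.7.11a, HISAT2 2.2.1 and featureCounts 2.0.6 without their roles. The program that computed FPKM is not given in the sources used here, and neither is the annotation release. The name of the ID column is the one Cufflinks writes, and the file's name points to removal of duplicate reads, a step that no label describes. FPKM is corrected for length and for mapped fragments, so a few very abundant transcripts can lower all other values in a library. The structural RNAs Rmrp, Rpph1 and Rn45s together held 8.1% to 18.5% of the summed FPKM per library, which is not a share of fragments. The largest share was in cKO replicate 1, where the tested genes still had the highest median. That median was 8.4 FPKM, against 6.85 to 7.09 in the other libraries. A value of exactly 0 can be a failed estimate here: Rn45s, the ribosomal RNA precursor, was listed at 0 in cKO replicate 2 and wild type replicate 2 and at 11790 FPKM or more in the other libraries.

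Raw counts and total mapped reads were not used here. Depth was estimated from the smallest steps of FPKM in 2438 genes with a single annotated transcript of at least 1500 bp, assuming 200 bp fragments. It came to 7100000, 10700000 and 12300000 fragments in cKO replicates 1, 2 and 3, and to 14100000, 14100000 and 11500000 in wild type replicates 1, 2 and 3. At these depths 1 FPKM of a transcript of 2 kb stands for about 14.2 fragments in the shallowest library and 28.2 in the deepest.

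Genes with a mean of at least 1 FPKM over all 6 libraries were tested, 12442 in all. Values were taken to log2(FPKM + 1), and cKO was compared with wild type by limma 3.58.1 in R 4.3.3 with an intensity trend, a two-sided moderated test and Benjamini-Hochberg adjustment, called at an adjusted p under 0.05. A fold change is on the log2(FPKM + 1) scale, which understates the change of genes with low values. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 35 lists with at least 3 tested members out of 37 lists that held 965 genes. Camera compares a list with all other tested genes, so its direction is relative to them, and the median log2 fold change of all tested genes was 0.08. At the preset correlation its p treats the genes of a list as nearly independent, so it is not a measure of the spread between libraries. The steps were tested on simulated libraries with the real means, residual spreads and library factors of 12442 genes, in which 200 genes were changed. Of genes changed 1.5, 2 and 3-fold, 13.7%, 63.3% and 89.7% were called without rescaling of the libraries. With median-of-ratios scaling 34.3%, 64.2% and 85.2% were called. Of unchanged genes 0.0719% were called without rescaling and 0.0539% with median-of-ratios scaling. The simulation left out correlation between genes. It planted more changes than the real fit without rescaling called, which loosens the adjusted threshold. The shares recovered can therefore be too high for that fit.

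The sample groups, tests, gene lists, alternatives and the rule for named genes were set before the data were examined. The rule names Hnrnpl, Hnrnpll and Mtor whatever their values. It adds, among called genes whose groups do not overlap, the 12 with the largest rise and the 12 with the largest fall, leaving out predicted loci and multigene families. It further adds 2 to 4 members with the smallest p of each list described. Alternatives were a pseudocount of 0.1 FPKM, no filter, a filter at a mean of 5 FPKM, median-of-ratios scaling (each library divided by the median of its ratios to the gene-wise geometric mean), quantile normalization, TPM rescaling, no intensity trend, library weights, a replicate block and leaving out each library. After seeing the data, a correction of each library for transcript length and GC content was added, as were a separate count after median-of-ratios scaling and its own alternatives. Length and GC content came from GENCODE M21 and gene coordinates from RefSeq, both on GRCm38, the assembly that mm10 names. Splice junctions, exons and isoforms are not analysed here, since the table holds 1 value per gene. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and figures.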

Results

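Transcript levels of whole day 1 ovaries were measured in 3 cKO and 3 wild type libraries, as FPKM per gene. Hnrnpl encodes an RNA-binding protein that regulates alternative splicing, and the series asks how its loss in germ cells bears on synapsis genes, on mTOR and on the formation of primordial follicles. Estimated depth ran from 7100000 fragments in cKO replicate 1 to 14100000 in wild type replicates 1 and 2. The FPKM of cKO replicate 1 summed to 335667, against 223845 to 246121 in the other 5 libraries. In that library short transcripts were higher: its median deviation from the gene mean was 0.35 (log2) in the sixth of genes with the shortest transcripts and 0.06 in the sixth with the longest. Pearson's r of log2(FPKM + 1) across the tested genes, which are not independent replicates, was 0.950 to 0.965 within groups and 0.947 to 0.953 between them.

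Hnrnpl, on chromosome 7 from 28808546 to 28822268 (GRCm38), was measured at 100.5, 81.5 and 85.2 FPKM in the cKO libraries and at 104.1, 93.8 and 101.9 FPKM in the wild type libraries. The log2 fold change of -0.17 (SE 0.13) did not pass the test (limma, adjusted p = 0.571), and the exact two-sided permutation test gave p = 0.2, with 0.1 the smallest p that 3 against 3 libraries allow. After median-of-ratios scaling the values were 85.5, 84.2 and 87.5 in cKO and 105.3, 95.4 and 107.4 in wild type, so that the groups did not overlap (exact p = 0.1). The log2 fold change was then -0.256 (SE 0.081) and did not pass either (limma adjusted p = 0.15, and from 0.089 to 0.816 over all alternatives). The tissue also holds somatic cells, and a gene-level FPKM does not show the floxed exons separately, so the value is a weak check of the labels. Hnrnpll, its paralog, stood at 14 ± 1.44 FPKM in cKO and 13.2 ± 0.542 FPKM in wild type (SD, n = 3; limma adjusted p = 0.743). Mtor, the kinase of the mTOR complexes, stood at 7.42 ± 0.209 and 7.61 ± 0.699 FPKM (SD, n = 3; limma adjusted p = 0.901).

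**Figure D1:**
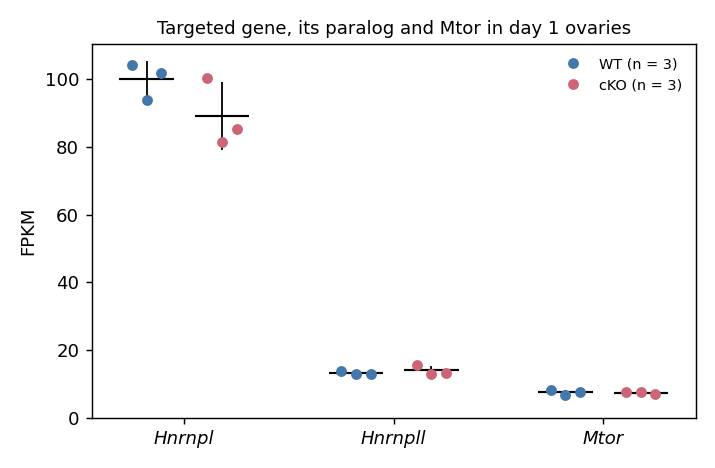
FPKM of Hnrnpl, Hnrnpll and Mtor in each library (points), with the mean (horizontal line) and SD (vertical line) of 3 wild type (blue) and 3 cKO (red) libraries. For Hnrnpl, cKO replicate 1 at 100.5 FPKM lies within the wild type range and the other 2 cKO libraries lie below it; after median-of-ratios scaling, not drawn, all 3 lie below it.

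The comparison of cKO with wild type ovaries asks which genes change when Hnrnpl is targeted in germ cells. Asns and Mthfd2 were among the 6 genes that rose, and Zp3 and Nlrp14 among the 9 that fell. Asns, the enzyme of asparagine synthesis, stood at 18.7 ± 5.54 FPKM in cKO and 5.88 ± 0.0702 FPKM in wild type (SD, n = 3), a log2 fold change of 1.48 (SE 0.18, limma adjusted p = 0.0437). Mthfd2, a mitochondrial enzyme of folate metabolism, rose from 1.42 ± 0.488 to 6.08 ± 1.36 FPKM, and Nupr1, a stress-induced transcriptional regulator, from 2.89 ± 1.12 to 13.3 ± 2.86 FPKM. Lin28a, an RNA-binding protein of germ and stem cells, rose by a log2 fold change of 1.04, and Extl1, a glycosyltransferase of heparan sulfate synthesis, by 1.08. Both lie near each other on chromosome 4, Lin28a from 134003330 to 134019196 and Extl1 from 134356373 to 134372547. Whether their rises are independent was not tested. Zp3, which encodes a zona pellucida glycoprotein, was lower at 2.19 ± 0.190 FPKM in cKO against 8.26 ± 2.23 FPKM in wild type, a log2 fold change of -1.51 (SE 0.18, limma adjusted p = 0.0437). Nlrp14, an oocyte gene, had a log2 fold change of -1.56, and Upk1b, a uroplakin of the ovarian surface epithelium list, one of -1.47. Hddc3, a nucleotide phosphohydrolase, had one of -0.90.

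In all, 15 of 12442 genes passed, 6 higher and 9 lower in cKO, and 14 of them changed at least 2-fold. All 15 had cKO values that did not overlap the wild type values, as had 22.6% of all tested genes, where chance gives 10%. A small p favours genes with such a gap, so it is no separate support for the calls. The rule left 1 riser and 5 fallers unnamed as predicted loci or multigene families. Nlrp4f is 1 of them and is named below as a list member. After median-of-ratios scaling 161 genes passed, 95 higher and 66 lower, all 15 among them, and after quantile normalization 236 passed, 131 higher and 105 lower. The count of 15 changed with the libraries used: it was 89 without cKO replicate 1 and 74 without cKO replicate 3, all 15 among them in both. It was 4 without cKO replicate 2, 2 without wild type replicate 1, 2 without wild type replicate 2 and 6 without wild type replicate 3, with 1, 1, 1 and 3 of the 15 among them.

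**Figure D2:**
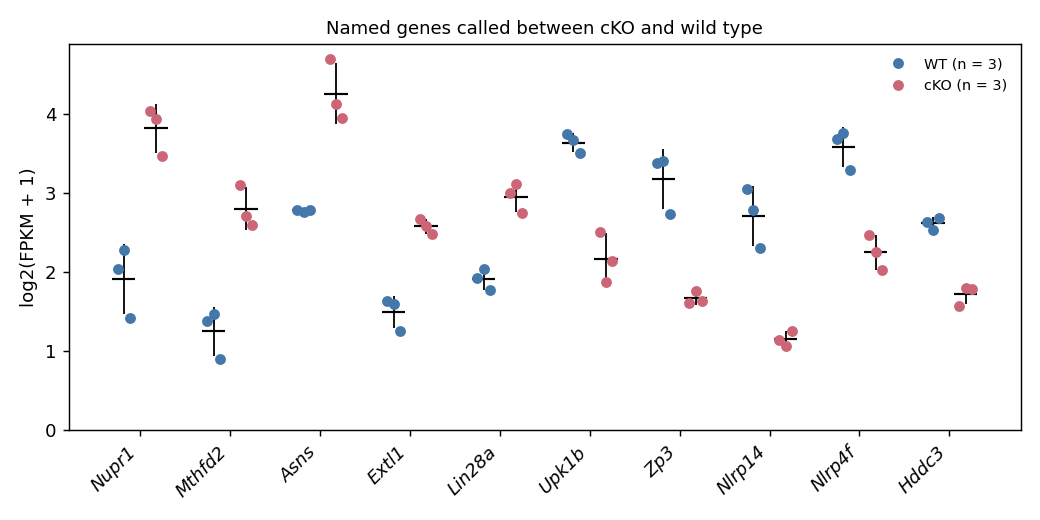
log2(FPKM + 1) of 10 genes called between groups, each point a library, with the mean (horizontal line) and SD (vertical line) of 3 wild type (blue) and 3 cKO (red) libraries. In each gene the cKO values lie apart from the wild type values. The genes other than Nlrp4f were chosen for this, so it adds no support to the calls.

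The meiotic synapsis list, which holds genes of the synaptonemal complex and chromosome axis, had 16 of 18 tested members with positive log2 fold changes and a median of 0.49 (camera adjusted p = 1.8e-05; adjusted p = 0.53 with an estimated correlation). None of its members passed over all genes and 3 were higher after median-of-ratios scaling; adjusted over the list alone 9 were higher and 0 lower, against 8 and 0 after scaling. Hormad1, a meiotic axis protein, stood at 4.70 ± 0.720 FPKM in cKO and 1.57 ± 0.550 FPKM in wild type (SD, n = 3), and Tex11, a meiotic protein, at 6.31 ± 1.45 and 2.86 ± 0.213 FPKM. The germ cell identity list had a median of 0.46, with 30 of 34 members positive (camera adjusted p = 4.1e-07; adjusted p = 0.68 with an estimated correlation). None passed over all genes and 5 were higher after scaling, while 17 members were higher and 1 lower when adjusted over the list alone, with or without scaling. Tex15 stood at 23.5 ± 3.83 FPKM in cKO and 11.5 ± 1.39 FPKM in wild type, and Mov10l1, a helicase of the piRNA pathway, at 26.1 ± 5.39 and 13.1 ± 0.671 FPKM. Ddx4, a germ cell marker of the same list that was chosen after its values were seen, stood at 4.80 ± 1.55 and 4.97 ± 0.638 FPKM (limma adjusted p = 0.881). The meiotic recombination list had a median of 0.20 over 23 members (camera adjusted p = 0.049; adjusted p = 0.83 with an estimated correlation), and 0 of them passed over all genes against 2 higher and 0 lower adjusted over the list alone. After scaling 2 were higher over all genes. Its members Ankrd31 and Sirt7 had log2 fold changes of 1.2 and 0.54. The call of this list ended with a filter at a mean of 5 FPKM (camera adjusted p = 0.16), with library weights (0.0578) and without cKO replicate 1 (0.0898), cKO replicate 2 (0.11), wild type replicate 1 (0.0821) or wild type replicate 3 (0.0607).

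The list of oocyte transcription factors and early oocyte genes had 12 members up and 12 down, with a median of -0.12 (camera adjusted p = 0.00085; adjusted p = 0.76 with an estimated correlation). Over all genes 3 of its 24 members fell, Zp3, Nlrp14 and Nlrp4f, and none rose. Nlrp4f belongs to a family of similar genes whose reads may be shared. Adjusted over the list alone, 4 were higher and 9 lower. After median-of-ratios scaling 2 rose and 6 fell over all genes, and 5 were higher and 10 lower adjusted over the list alone. The list's call ended with a filter at a mean of 5 FPKM (camera adjusted p = 0.474), with TPM rescaling (0.0542) and without cKO replicate 3 (0.0868). Gdf9, an oocyte growth factor, stood at 2.61 ± 0.172 FPKM in cKO and 5.54 ± 1.47 FPKM in wild type (SD, n = 3; limma adjusted p = 0.114).

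Several somatic marker lists were lower in cKO relative to all other genes. The stroma and mesenchyme list had 25 of 29 members negative and a median of -0.25 (camera adjusted p = 3.3e-10; adjusted p = 0.53 with an estimated correlation), with 0 members passing over all genes and 5 lower adjusted over the list alone. After median-of-ratios scaling these counts were 4 and 21, and with the length and GC correction, chosen after seeing the data, the estimated correlation gave adjusted p = 0.032. Col5a2, a fibrillar collagen, stood at 19.6 ± 1.12 FPKM in cKO and 26 ± 1.30 FPKM in wild type (SD, n = 3), and Pdgfra, a growth factor receptor, at 26.1 ± 2.05 and 35.0 ± 1.34 FPKM. The surface epithelium list had a median of -0.36 over 18 members (camera adjusted p = 4.8e-09; adjusted p = 0.53 with an estimated correlation). Upk1b alone fell over all genes, while 1 member was higher and 9 lower adjusted over the list alone. After scaling 5 fell over all genes, and 2 were higher and 14 lower over the list alone. Upk3b stood at 16.0 ± 4.35 and 31.8 ± 3.19 FPKM. Endothelial cells had a median of -0.32 over 21 members (camera adjusted p = 1.2e-07; adjusted p = 0.53 with an estimated correlation), with 0 called either way, and 14 lower over the list alone after scaling; Egfl7 and Robo4 had log2 fold changes of -0.43 and -0.44. Pericytes and smooth muscle had a median of -0.23 over 12 members (camera adjusted p = 6e-07; adjusted p = 0.47 with an estimated correlation), with 0 passing over all genes and 4 lower adjusted over the list alone, among them Acta2, smooth muscle actin, at 12.7 ± 0.893 and 17.8 ± 0.870 FPKM. After scaling 1 fell over all genes, and 1 was higher and 7 lower over the list alone.

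Lists of cell interaction and growth were also called lower. Basement membrane and cell adhesion had a median of -0.15 over 26 members (camera adjusted p = 1.1e-05; adjusted p = 0.6 with an estimated correlation), and Notch signalling one of -0.23 over 18 members (camera adjusted p = 0.00013; adjusted p = 0.53 with an estimated correlation). In the Notch list the ligand genes Jag2 and Jag1 went opposite ways, with log2 fold changes of 0.82 and -0.50 that did not pass over all genes. The mitotic cell cycle list had a median of -0.09 over 40 members (camera adjusted p = 0.00068; adjusted p = 0.76 with an estimated correlation), and its call ended without cKO replicate 3 (camera adjusted p = 0.0501). Mki67, a proliferation marker, stood at 12 ± 1.22 and 16.9 ± 1.09 FPKM (SD, n = 3). Pregranulosa and granulosa cells had a median of -0.06 over 38 members (camera adjusted p = 0.0072; adjusted p = 0.76 with an estimated correlation). Their members Lhx9 and Notch3 stood at 10.2 ± 0.471 and 15.8 ± 0.318 FPKM and at 4.95 ± 0.671 and 7.48 ± 0.617 FPKM. Adjusted over the list alone, the members higher and lower numbered 1 and 2 for basement membrane, 1 and 3 for Notch, 0 and 0 for the mitotic cycle and 0 and 2 for granulosa cells. After scaling they numbered 1 and 11, 1 and 9, 0 and 6, and 2 and 8 in the same order. Over all genes 0 members of these lists passed, and after scaling 0 rose and 0 fell for basement membrane, 1 and 1 for Notch, 0 and 1 for the mitotic cycle and 1 and 2 for granulosa cells. Erythroid cells (6 members, median -0.45, camera adjusted p = 0.021), macrophages and leukocytes (15 members, -0.16, 0.032) and oviduct, rete and mesonephric epithelium (7 members, -0.25, 0.032) were called lower with 0 members passing over all genes. With an estimated correlation their adjusted p were 0.53, 0.68 and 0.68. Of the 6 erythroid members 2 were positive and 4 negative. Among them Hba-a1 and Hba-a2 are similar genes whose reads may be shared. In wild type replicates 1, 2 and 3 Hba-a1 stood at 343.2, 69.2 and 433.1 FPKM and Hba-a2 at 109.2, 421.4 and 77.3 FPKM. Adjusted over the list alone, the oviduct list had 1 member higher and 1 lower and the other 2 lists had none; after scaling the oviduct list had 1 and 4 and the erythroid list 0 and 2. The calls ended after median-of-ratios scaling (camera adjusted p = 0.0524, 0.119 and 0.0524). The erythroid call also ended without wild type replicate 1 (0.064). The oviduct call ended with quantile normalization (0.0702), TPM rescaling (0.068) and without cKO replicate 3 (0.0501), wild type replicate 1 (0.177) or wild type replicate 3 (0.0795). The macrophage call ended with no filter (0.197), quantile normalization (0.27), TPM rescaling (0.382), library weights (0.0717) and without cKO replicate 1 (0.146), cKO replicate 3 (0.0607) or wild type replicate 3 (0.0809).

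Stress and metabolic lists were called higher. In the unfolded protein and integrated stress response list, Asns and Mthfd2 rose and 23 of 25 members did not pass, with a median of 0.16 (camera adjusted p = 0.0073; adjusted p = 0.76 with an estimated correlation). After scaling 6 rose over all genes. Adjusted over the list alone 8 were higher and 0 lower, against 11 and 2 after scaling, among them Chac1, a glutathione-degrading enzyme, at 3.36 ± 0.966 and 0.635 ± 0.35 FPKM (SD, n = 3), and Trib3, a pseudokinase induced by stress, at 2.90 ± 0.791 and 0.710 ± 0.247 FPKM. The list's call ended with a filter at a mean of 5 FPKM (camera adjusted p = 0.18). Nuclear oxidative phosphorylation (35 members, median 0.26, camera adjusted p = 0.0073), translation factors (27 members, 0.20, 0.019) and glycolysis (16 members, 0.23, 0.023) had 0 members that passed over all genes. With an estimated correlation their adjusted p were 0.84, 0.84 and 0.76. Adjusted over the list alone 0, 0 and 2 of their members were higher, and 0, 3 and 2 after scaling. The oxidative phosphorylation call ended without cKO replicate 1, the library with higher short transcripts (camera adjusted p = 0.184), and with library weights (0.0578), and the glycolysis call without wild type replicate 2 (0.0817). The translation call ended without cKO replicate 1 (0.137) or wild type replicate 1 (0.064), with a filter at a mean of 5 FPKM (0.0748), quantile normalization (0.0582) and library weights (0.0578). With the length and GC correction, chosen after seeing the data, the calls stayed. Camera adjusted p was then 0.033 for oxidative phosphorylation, 0.0078 for translation factors and 0.012 for glycolysis. Ndufb8 stood at 63.1 ± 9.89 and 44.2 ± 6.46 FPKM, Eif5 at 36.0 ± 4.96 and 26.1 ± 1.17 FPKM and Pdk1, a kinase that limits pyruvate use, at 14.4 ± 2.19 and 9.17 ± 1.43 FPKM.

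**Figure D3:**
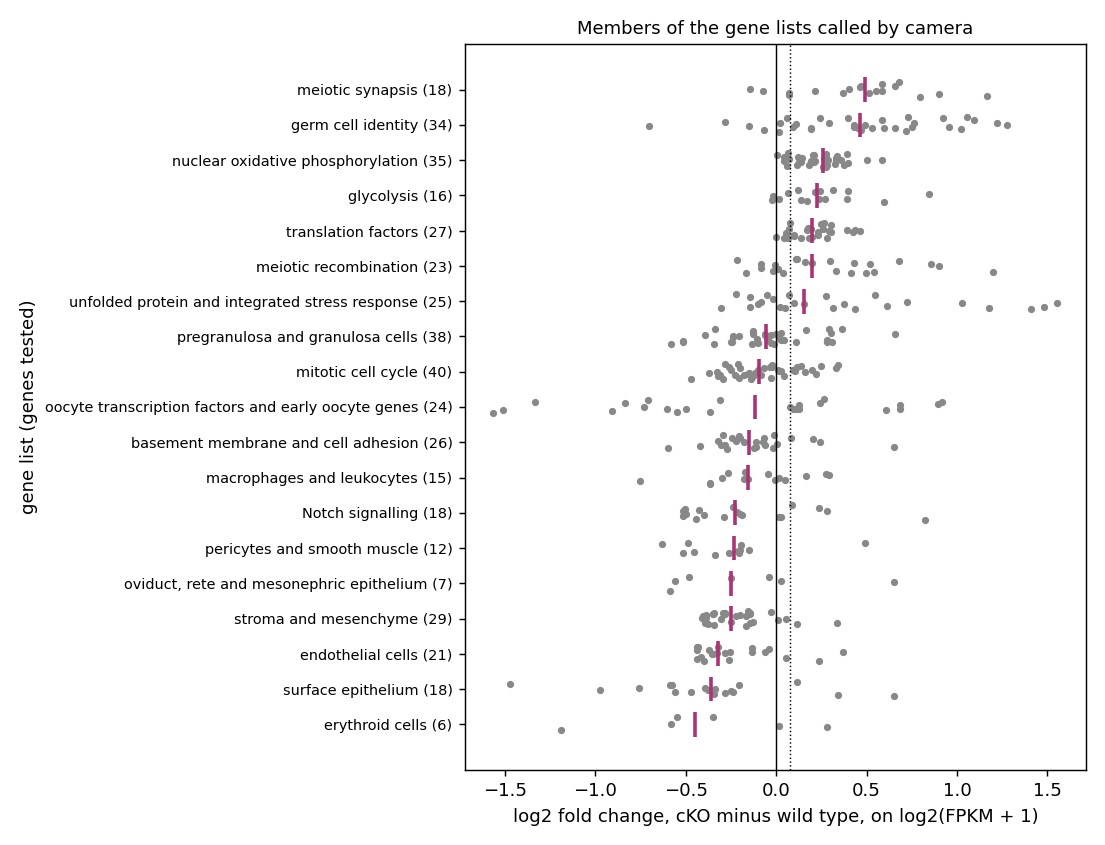
log2 fold change of each tested member (grey points) of the 19 gene lists called by camera, with the list's median (purple bar); the solid line marks 0 and the dotted line the median of all tested genes, 0.08. Meiotic synapsis has the highest median, 0.49, and erythroid cells the lowest, -0.45.

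In all 19 of 35 lists were called, 7 higher and 12 lower, and 0 with an estimated correlation or with fry, a rotation test. A split of the libraries that mixed the groups, counted after the results were seen, called 17 lists at the preset correlation. The number of lists called thus hardly sets the real groups apart. With the length and GC correction the stroma list was called with an estimated correlation (adjusted p = 0.032). The mTOR and PI3K-AKT list was not called (50 members, median 0.07, camera adjusted p = 0.67). Adjusted over the list alone 2 of its members were higher and 0 lower, and its smallest p belonged to Sesn2, Kit and Eif4ebp1, with log2 fold changes of 0.61, 0.69 and 0.83. After median-of-ratios scaling the list was still not called (camera adjusted p = 0.75), while Kit and Sesn2 passed over all genes (limma adjusted p = 0.0223 and 0.0387; 0.139 and 0.127 before) and 3 members were higher and 0 lower adjusted over the list alone. The hnRNP family (29 members, median 0.03, camera adjusted p = 0.26) and the spliceosome and SR proteins (53 members, 0.06, 0.78) were not called, and Hnrnpm and Esrp1 had the smallest p in each. Esrp1 passed over all genes after scaling (limma adjusted p = 0.0278; 0.101 before). The hnRNP median was positive and its camera direction down, since camera compares with other genes, and the list was called lower after quantile normalization (adjusted p = 0.0041), after TPM rescaling (0.00994) and without cKO replicate 1 (0.0252). Further lists were not called: p53 targets and apoptosis (camera adjusted p = 0.22), ribosomal proteins (0.22), cholesterol synthesis (0.25), autophagy and lysosome (0.26), immediate early and dissociation stress (0.26), testis cord and Leydig cells (0.29), adipose and skeletal muscle (0.43), interferon response (0.67), steroidogenic cells (0.78), replication-dependent histones (0.81), DNA damage response (0.89), TGF-beta, BMP and activin signalling (0.075) and nuclear retained and structural noncoding RNA (0.088). Some of these were called under an alternative. Higher were ribosomal proteins after median-of-ratios scaling (0.0472), p53 targets (0.0371) and autophagy (0.0398) with no filter, and testis cord and Leydig cells with a filter at a mean of 5 FPKM (0.00439), quantile normalization (0.0457) and TPM rescaling (0.0185). Lower were immediate early genes with quantile normalization (0.0101) and TPM rescaling (0.0421), TGF-beta signalling with quantile normalization (0.049), noncoding RNA without cKO replicate 3 (0.0153) and histones without cKO replicate 1 (0.0035). No mitochondrially encoded gene of its list could be matched to the table's symbols, and the 8 Y-linked genes were all below the filter.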

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

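The length and GC correction and the count after median-of-ratios scaling with its alternatives were chosen after seeing the data; the other settings were planned. Where a value moved, the cause was not tested unless stated. The 15 genes changed became 34 with a pseudocount of 0.1 FPKM, 23 with a filter at a mean of 5 FPKM, 161 with median-of-ratios scaling, 236 with quantile normalization, 149 with TPM rescaling (56 higher, 93 lower), 172 with library weights and 279 with the length and GC correction; each of these but the filter at 5 FPKM, which tested 7883 genes and kept 9, held all 15. They became 5 with no filter, which tested 20166 genes, and 5 with no intensity trend. At an adjusted p under 0.1 there were 94, and 1761 at an unadjusted p under 0.05. Leaving out 1 library gave 2 to 89, with fewer samples in each fit. The 14 genes changed at least 2-fold became 27, 37, 46, 55, 39 and 39 under the pseudocount, median-of-ratios scaling, quantile normalization, TPM rescaling, library weights and the length and GC correction, 4 with no filter, 5 with no intensity trend, and 2 to 43 with 1 library left out. TPM rescaling moved the median log2 fold change of all genes by -0.19, to -0.115, so its changes are relative to that shift. After median-of-ratios scaling the 161 genes became 41 with no filter, 88 with no intensity trend, 311 with library weights and 5 to 209 with 1 library left out: 95, 24 and 209 without cKO replicates 1, 2 and 3, and 5, 40 and 28 without wild type replicates 1, 2 and 3. The 19 lists called stayed between 15 and 20 except with an estimated correlation and with fry, which called 0, and with both the length and GC correction and an estimated correlation, which called 1, the stroma list. Hnrnpl stayed negative and uncalled in every setting, from -0.11 to -0.38.

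Same-numbered libraries did not deviate together: the correlations of their residuals were -0.01, 0.04 and 0.07. These values show no pairing by number, but 3 libraries per group are too few to exclude it. With a replicate block 2 genes passed, 2 of them changed at least 2-fold, and 25 passed after median-of-ratios scaling.

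Signs turned only where neither value was called, except in histones without cKO replicate 1. Hnrnpll went to -0.0024, -0.03 and -0.12 under median-of-ratios scaling, quantile normalization and TPM rescaling, Mtor ran from -0.09 to 0.02 with 1 library left out (0.02 without wild type replicate 1), and Ddx4 from -0.27 to 0.09 (0.09 without cKO replicate 3 and 0.02 without wild type replicate 2). As mean log2 fold change against all other genes, the spliceosome list went to -0.01 with the filter at 5 FPKM, -0.0025, -0.03 and -0.0036 under the same 3 scalings and -0.0049 without wild type replicate 1. The DNA damage list went to 0.0031 with the pseudocount, 0.03 with no filter, 0.0054, 0.02 and 0.01 without cKO replicates 2 and 3 and wild type replicate 2, and 0.0076 with the length and GC correction. Histones went to -0.006 with the pseudocount, -0.02 with quantile normalization, -0.14 with library weights, -0.21 (camera adjusted p = 0.0035) without cKO replicate 1 and -0.01 without wild type replicate 1, up to 0.19 without cKO replicate 3. Noncoding RNA went to 0.03 with no filter, 0.06 with the filter at 5 FPKM, 0.02 with library weights, 0.05, 0.02 and 0.01 without cKO replicate 1 and wild type replicates 1 and 3, down to -0.1 without cKO replicate 3. Steroidogenic cells went to -0.03 and the interferon response to 0.1 with the filter at 5 FPKM, and adipose and skeletal muscle to -0.04 with no filter. Of all other values of named genes, 687 kept their side of the threshold, 163 gained a call and 67 lost one; of lists, 484, 13 and 35.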

Other observations

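In this part the means of lists and sets per library, the oocyte counts after scaling with a library left out, the comparison of hairpins and the counts of other splits were chosen after the results were seen; the other tests were set before. First tests on sets picked after the results, of zona and maternal-effect genes and of targets of ATF4, and a count of fallers in the oocyte list were dropped for means of fixed lists. After median-of-ratios scaling, further genes were called that the text had not named, and they were chosen after their values were seen. Ckb, brain-type creatine kinase, stood at 66.7 ± 17.3 FPKM in cKO and 25.4 ± 0.825 FPKM in wild type (SD, n = 3; limma adjusted p = 0.0112 after scaling, 0.0536 before). Terc, the telomerase RNA, stood at 30.0 ± 7.19 and 11.6 ± 1.08 FPKM (0.0115 after scaling, 0.0502 before). Dazl, a germ cell RNA-binding protein, stood at 27.8 ± 11.1 and 10.3 ± 1.44 FPKM (0.043 after, 0.127 before). Lower in cKO were Ptges, a prostaglandin E synthase, at 4.22 ± 1.05 and 8.39 ± 0.172 FPKM (0.02 after, 0.0822 before) and Il1b, a cytokine, at 0.523 ± 0.22 and 2.39 ± 0.786 FPKM (0.0479 after, 0.101 before). In the testis cord and Leydig list, which was not called, Aard stood at 40.1 ± 6.67 and 22.1 ± 1.32 FPKM and Gstm6 at 184 ± 41.6 and 109 ± 1.23 FPKM. The scaled counts depend on single libraries, down to 5 genes without wild type replicate 1.

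The germ cell identity and meiotic synapsis lists had higher means in cKO, with 0 of 34 and 0 of 18 members passing over all genes and both list calls lost with an estimated correlation (adjusted p = 0.68 and 0.53). Without cKO replicate 1 the mean over both lists was still higher by 0.33 (SE 0.1) on the median-of-ratios scale, which argues against that library's length trend as the whole cause. A larger share of germ cells in the cKO tissue stays open: the mean of 122 genes of the granulosa, stroma, steroidogenic, surface epithelium, endothelial and pericyte lists differed by -0.23 (SE 0.02), but these lists did not move alike, with stroma at -0.29 (SE 0.02), granulosa at -0.13 (SE 0.02) and steroidogenic cells at 0.05 (SE 0.08). The mean of the oocyte list differed by -0.29 (SE 0.12), which a larger share of germ cells alone would not give. Members of the oocyte list went both ways, with 6 of 24 lower and 2 higher after scaling. The lower and higher members numbered 3 and 2, 2 and 0, and 3 and 5 without cKO replicates 1, 2 and 3. They numbered 0 and 0, 2 and 0, and 4 and 0 without wild type replicates 1, 2 and 3. Without wild type replicate 1 only 4 genes of any kind fell. The oocyte list does not settle the share of germ cells. An effect of the genotype and a difference in age or litter, which the labels do not give, stay open and were not tested.

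The unfolded protein and integrated stress response list was called higher, with 2 of 25 members passing over all genes, and its call was lost with an estimated correlation (adjusted p = 0.76). Its mean was 4.22, 4.13 and 4.12 in cKO and 3.89, 3.88 and 3.84 in wild type on the median-of-ratios scale, and without cKO replicate 1 the difference was 0.26 (SE 0.02), which argues against that library's length trend as the whole cause. Handling stress before lysis stays open: the immediate early list differed by -0.07 (SE 0.06), too near 0 to decide, as no size is set for its rise. The list's 8 genes of endoplasmic reticulum folding and quality control differed by -0.09 (SE 0.05), and by -0.12 (SE 0.05) without cKO replicate 1. The whole list, which holds them, differed by 0.29, a gap of -0.38 (SE 0.04). These 8 genes were thus not higher in cKO and did not carry the rise of the list. For these 8 genes the values argue against a rise of the folding machinery as the cause. They were grouped after the results were seen, so other folding genes are not covered. An effect of the genotype was not tested apart from these explanations.

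The call with the smallest p was Mir6935, a hairpin of 64 bp on chromosome 11 from 120347350 to 120347413 (GRCm38), which lies in an intron of Actg1, next to an exon, on the same strand. It was listed at 0 in each cKO library and at 48.0, 57.5 and 37.7 FPKM in the wild type libraries (limma adjusted p = 4.67e-06), at most 52 fragments if taken over its full length of 64 bp. Whether the wild type values of Mir6935 stand for 1 or a few fragments stays open. In 1 of the 3 wild type libraries, replicate 3, the value equals, within 0.1%, that of another hairpin of the same length. In replicate 2 the 1 other such hairpin above 0 had another value, and in replicate 1 there was none. The values of 0 in cKO can be failed estimates, which was not tested. Of 1162 hairpins listed, 1008 were at 0 in all libraries and 88 were above 0 in 1 library only. A pair of pseudogenes on chromosome 8, 6820431F20Rik (20268286 to 20297432) and 2610005L07Rik (20385782 to 20424814), fell together with log2 fold changes of -1.09 and -1.08, and 26.7% of the 31-base words of the latter's transcripts occur in the former's, too few to settle whether reads are shared. A strain or haplotype difference at these loci was not tested.

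Other splits of the 6 libraries into 3 and 3 number 10 with the real one, too few for a share under 0.05. In each of the 4 counts 1 of the 10 splits, the real one, reached the real value. The real split gave 15 genes and the highest other 3; for genes changed at least 2-fold it gave 14 against 3; for lists called 19 against 17; and after median-of-ratios scaling 161 against 3.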
